A study of Mus musculus with 12 samples.

How the data were processed

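RNA sequencing of mouse embryonic fibroblasts, cells grown out of mouse embryos and cultured here in medium with 10% fetal bovine serum, was analysed in 12 libraries of 4 groups with 3 libraries each. Per the labels, the cells came from a C57BL/6 background and total RNA was extracted with a Qiagen kit and made into libraries with standard Illumina protocols. The groups carried the labels Control, shPten (a short hairpin RNA against Pten), D1TA and D1TA_shPten. The series title names a cyclin D1 mutant that cannot be phosphorylated, and D1TA is read here as the label of that mutant. 4-hydroxytamoxifen, a ligand used to switch on inducible Cre recombinase, was named only in the descriptions of the D1TA groups, and no control hairpin was named for the groups without shPten. The descriptions of all 4 groups carry the same genotype term, D1fl-WT.

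The deposited table held 1 value per gene and library for 48432 genes, and its header named no unit. The values were taken as FPKM, fragments scaled to the length of the transcript and the size of the library, because the authors used Cufflinks and Cuffdiff after alignment with STAR to mm10, per the submitters' processing notes, and because the values were neither whole nor of equal sum. Software versions, strandedness and the annotation release were not given in the sources used here. Whether Cuffdiff scaled the libraries to each other was not given either. Of the gene identifiers, 99.2% were found in GENCODE release M21 without regard to version and 83.8% with the same version, and that annotation of GRCm38 (the same assembly as mm10) supplied coordinates and exons.

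Of the 3 Control columns, the last ones in the table had the same header, so they were used as Control libraries without a replicate number (a and b). They shared no identical value above 0 among 23238 genes and correlated at r = 0.9644 across tested genes on the log2 scale, so they were treated as separate libraries. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No paired analysis was possible against Control or for the interaction, because these Control columns carry the same number.

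Read counts were not part of the table. The value of a single fragment in 1849 genes with 1 annotated transcript and at least 3000 exonic bases put the depth at about 23200000 to 30600000 fragments per library. That estimate is approximate, because Cufflinks assigns fractions of fragments and may rescale libraries. An exact or near 0 could be a failed estimate: Gapdh was listed at 0.368 to 0.883 FPKM and mt-Co1, mt-Cytb and mt-Atp6 at 0, although fibroblasts use these genes.

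Tests were run on log2(FPKM + 1) for the 13617 genes with at least 1 FPKM in 3 or more libraries. One limma model (version 3.58.1 in R 4.3.3, trended and robust variance) with the 4 groups as its only term was fitted to the 12 libraries, and 6 comparisons, including the interaction of D1TA and shPten, were drawn from it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. Pten and Ccnd1 were also compared between 6 and 6 libraries with an exact two-sided permutation test of 924 splits.

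A total of 32 gene lists from textbook knowledge, 7 of them markers of other cell types, were fixed before the data were examined, as were the main test, most of the alternatives and the rule for named genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 29 lists that had at least 3 measured members. Mitochondrially encoded transcripts (0 measured), endothelial markers (2) and skeletal muscle markers (1) were not tested. Named genes were Pten and Ccnd1, the 10 highest and 10 lowest fold changes against Control and the 5 highest and 5 lowest in the other comparisons. These had to be called, to reach a mean of 2 FPKM in the higher group, to have groups that did not overlap (not asked for the interaction) and to have a usual symbol. Up to 4 called members of each called list with the smallest adjusted p were added, and members of lists not called where at most 3 were called.

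In simulated data with known changes over 13617 genes for shPten against Control, the same fit recovered 87% of 100 genes changed by 0.5 and 93% of 100 genes changed by 1 on the log2 scale, and called 8 unchanged genes. The simulated noise was normal and independent between genes, with no shift between libraries. In the real comparison 47.3% of genes were called, so these rates need not hold there. The alternatives were quantile normalization, equal medians, no filter and a mean of at least 5 FPKM, limma without trend, pseudocounts of 0.1 and 0.5, only the groups compared, a replicate block, a minimum fold, and each library left out in turn. Added after seeing the data were the 5.8S ribosomal RNA level as a covariate, leaving out D1TA replicate 1 and D1TA_shPten replicate 1 together, leaving out genes under 300 exonic bases, the fit of 9 libraries without the block, permutation of the labels within each arm for Pten and Ccnd1, and the list test on the interaction.

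Paralogs, pseudogene copies and overlapping genes may share reads. Without stated strandedness this also holds for antisense partners: exons of another gene on the opposite strand cover 23.4% of the exonic bases of Ccnd1, 30.7% of those of Cdkn1c and 67.9% of those of Tagln. On the same strand, exons of another gene cover 30.8% of those of Stat1, 34.4% of Ctsd, 46.4% of Scarna3a and 99.5% of Rnu3a. The ribosomal protein, Lce1 and Ifi27 families, Rnu3a and n-R5-8s1 are uncertain for the same reason.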

Results

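The study measured RNA in mouse embryonic fibroblasts in a crossed design, with and without the D1TA label (the cyclin D1 mutant) and with and without the shPten label, in 3 libraries per group. Estimated depth was 23200000 to 30600000 fragments per library. The first principal component, with 24.8% of the variance, separated the 6 libraries labelled shPten (17.5 to 25.1) from the other 6 (-25.8 to -17.6).

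Pten and Ccnd1, the genes that the labels target, were examined first. Pten, the lipid phosphatase that opposes PI3K (ENSMUSG00000013663.7, chromosome 19, 32757497 to 32826160, plus strand, GRCm38), was not lower in the libraries labelled shPten. Its level was 23.3 ± 1.23 FPKM in Control, 25 ± 0.894 in shPten, 26.6 ± 1.97 in D1TA and 25 ± 1.11 in D1TA_shPten (SD, n = 3 each). The 6 libraries with the shPten label did not differ detectably from the 6 without it (exact two-sided permutation p = 0.913). The fitted fold of shPten over Control was 1.07, with a range of 2 standard errors from 0.991 to 1.16. That of D1TA over Control was 1.14 (1.05 to 1.23, limma adjusted p = 0.0528). Pten differed between D1TA_shPten and D1TA by a log2 of -0.0862 (limma adjusted p = 0.244), with the same difference in the 9 libraries other than Control, where the adjusted p was 0.247 without and 0.0392 with the replicate number as a block. With quantile normalization this difference was -0.146 (limma adjusted p = 0.0304). Every direction below is that of libraries labelled shPten. Ccnd1, which encodes cyclin D1 (ENSMUSG00000070348.5, chromosome 7, 144929931 to 144939925, minus strand), was 181 ± 1.82 FPKM in Control, 135 ± 0.488 in shPten, 194 ± 1.86 in D1TA and 141 ± 2.30 in D1TA_shPten. It was lower in the 6 libraries labelled shPten (138 ± 3.72 against 187 ± 7.02 FPKM, exact two-sided permutation p = 0.00216). With the D1TA label Ccnd1 was slightly higher in each arm: 192 to 195 FPKM in D1TA against 179 to 183 in Control, and 139 to 143 in D1TA_shPten against 134 to 135 in shPten. The limma folds were 1.07 (range of 2 standard errors 1.04 to 1.10, adjusted p = 0.00926) and 1.05 (1.02 to 1.07, adjusted p = 0.0841). For the latter the adjusted p by limma in the 9 libraries other than Control was 0.133 without and 0.0485 with the replicate block, and it was 0.0333 in all 12 libraries with quantile normalization. The exact permutation of all 12 libraries (p = 0.569) leaves the shPten difference in the spread, and with labels permuted within each arm, chosen after seeing the data, the exact p was 0.005, the smallest that 400 splits can give. Total Ccnd1 RNA does not separate the mutant from the normal allele.

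**Figure D1:**
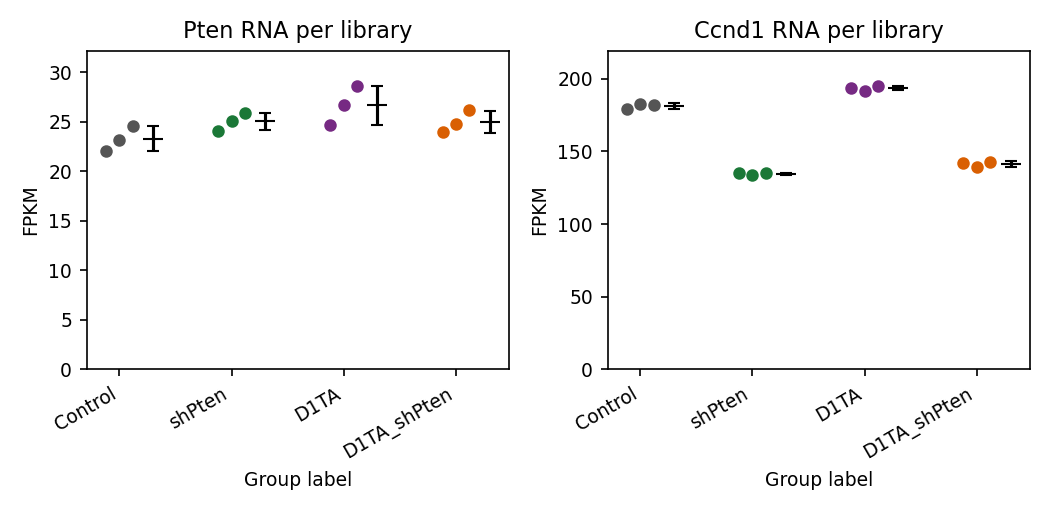
Pten and Ccnd1 RNA in FPKM (vertical axes, starting at 0) by group label; points are libraries, and the bar beside them is the mean with its SD (n = 3). Pten lies between 22.1 and 28.6 FPKM, with D1TA (24.7 to 28.6) above Control (22.1 to 24.6) and no fall in the groups labelled shPten against Control. Ccnd1 lies at 135 and 141 FPKM in the groups labelled shPten against 181 and 194 FPKM in the others.

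Libraries labelled shPten differed from Control in matrix, contractile and lipid genes. All 24 measured genes of cholesterol synthesis rose, with a median fold of 1.80. Among them were Cyp51 (log2 1.42 ± 0.04, SE), Hmgcs1 (1.20 ± 0.04), Sqle (1.15 ± 0.03) and Ldlr, the LDL receptor. Of 32 collagens and matrix genes 29 rose and 1 fell, including Col8a1 (1.58 ± 0.04), Col3a1 (1.04 ± 0.02) and Col6a1 (1.03 ± 0.03). All 19 contractile genes rose, including Cnn1 (1.42 ± 0.04), Actg2 (1.27 ± 0.03) and Acta2, smooth muscle actin (0.78 ± 0.02). TGF-beta targets had 11 genes up and 2 down of 18, led by Ltbp2 (1.32 ± 0.03). E2F targets, which serve DNA replication, had 21 up and 1 down of 34, with Mcm2 at 0.43 ± 0.04 and Uhrf1 at 0.42 ± 0.03. Ribosomal protein genes fell in 23 of 29 cases, Rps19 by 0.41 and Rps5 by 0.35 on the log2 scale.

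The genes with the highest fold changes were Wisp2, a secreted CCN family protein, at 48.7 ± 0.540 against 6.30 ± 0.668 FPKM in Control, and Cemip, a hyaluronan-degrading factor, at 29.2 ± 0.237 against 4.33 ± 0.0408 FPKM (SD, n = 3). Next came Rnu3a, a small nucleolar RNA with near-identical copies, Abi3bp, Penk (proenkephalin), Mfap4, Cpxm1, the chemokine Cxcl14, Dkk3 and Myom1, at log2 1.92 to 2.48. The chemokines Ccl5 and Cxcl10 were lowest, at 1.64 ± 0.570 against 22.1 ± 2.80 and 1.87 ± 0.335 against 12.2 ± 0.231 FPKM. They were followed by Cldn4, Wfdc2, Cdkn1c (the CDK inhibitor p57), Cxadr, Tnfaip3, Rsad2, Gap43 and Fosb, at log2 -2.07 to -1.41. All 4 measured epithelial markers fell, Cldn4 by 2.07, Krt18 by 1.26, Krt7 by 0.92 and Krt19 by 0.71 on the log2 scale. Of 6 hematopoietic markers 4 were lower, including Lyz2 at -0.75 ± 0.05 and Tyrobp at -0.74 ± 0.12. These marker changes accompanied the gene groups above, and whether the cultures differed in their mix of cells was not tested.

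In all, limma called 6435 of 13617 genes in this comparison, 3503 higher and 2932 lower, of which 237 changed at least 2-fold. The share higher was 54.4%, and 46.4% with equal medians or quantile normalization, so the majority direction depends on the scaling. Camera called 14 of 29 lists. Cholesterol synthesis (adjusted p = 0.00127 with an estimated correlation), matrix (p = 0.000353), contractile genes (p = 0.00127), TGF-beta targets (p = 0.0229), E2F targets (p = 0.0153), ribosomal proteins (p = 0.00259) and epithelial markers (p = 0.0175) held with an estimated correlation. The other calls did not: G2/M and mitosis had 28 of 30 genes higher (adjusted p = 0.087 with an estimated correlation), fatty acid synthesis 9 higher and 1 lower of 15 (p = 0.117), ER chaperones 11 higher and 2 lower of 19 (p = 0.423) and DNA repair 10 higher and 1 lower of 25 (p = 0.423). Among lists lower by limma and camera, glycolysis and hypoxia had 12 lower and 5 higher of 24 (adjusted p = 0.0643 with an estimated correlation), NRF2 targets 9 lower and 4 higher of 18 (p = 0.117) and hematopoietic markers 4 of 6 (p = 0.128). Adjusted over the list alone, all 24 cholesterol genes, 30 matrix genes and 25 E2F targets were higher. Among lists tied to the labels, FOXO targets (10 higher and 8 lower of 22), PI3K-AKT-mTOR components (7 higher and 4 lower of 27), G1 cyclins and CDK inhibitors (7 higher and 7 lower of 15) and factors of cyclin D1 turnover (4 higher and 3 lower of 18) were not called.

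D1TA without shPten was compared with Control to see the change with the cyclin D1 mutant. Interferon response genes rose in 18 of 28 cases and fell in 2, with a median fold of 1.27. Rtp4 (log2 0.60 ± 0.05), the signal transducers Stat1 (0.58 ± 0.04) and Stat2 (0.53 ± 0.04) and the RNA sensor Ddx58 (0.45 ± 0.03) were among those that rose. Genes of G2/M and mitosis fell in 19 of 30 cases and rose in none, with Plk1, a mitotic kinase, lower by a log2 of -0.29 ± 0.04 and Cdk1 at -0.19 ± 0.03. E2F targets fell in 9 of 34 cases, glycolysis and hypoxia genes in 9 of 24 and contractile genes in 5 of 19, with Tagln at -0.18 ± 0.02. Targets of p53 rose in 11 and fell in 2 of 27 cases, including Dcxr (0.46 ± 0.05), Fas (0.43 ± 0.06) and Btg2 (0.40 ± 0.04). Lysosome genes rose in 11 of 24, with Ctsb (0.29 ± 0.03) and Ctsd (0.25 ± 0.02), both cathepsins. Epithelial markers fell in all 4 cases, with Krt7 at -0.47 ± 0.07 and Cldn4 at -0.42 ± 0.09.

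Ranked by fold, Rnu3a was highest (154 ± 75.2 against 50.9 ± 20.4 FPKM), followed by Il1rn, the interleukin-1 receptor antagonist (6.03 ± 1.09 against 1.90 ± 0.270 FPKM), Ginm1, Pltp, Wisp2, Tmem119, Notch3, Cox6b2, Ifi27 and Gas1, at log2 0.76 to 0.995 for the last 8. The lowest were Enpp2, which makes lysophosphatidic acid (1.62 ± 0.215 against 3.77 ± 0.193 FPKM), Tigit, Ccl5, Fosb, U90926, Lce1h, Sprr2k, Cxcl10, Rsad2 and Krt7, at log2 -0.87 to -0.47. Ribosomal RNA features were higher with D1TA: n-R5-8s1, a 5.8S copy, was at 18710 to 34330 FPKM in D1TA, 8214 to 29770 in D1TA_shPten, 2234 to 9095 in Control and 773.2 to 2915 in shPten.

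Limma called 1852 genes, 1092 higher and 760 lower, and 10 of them changed at least 2-fold. Camera called 14 lists, of which 11 held with an estimated correlation. Matrix genes (11 higher and 1 lower of 32), YAP-TEAD targets (3 higher and 9 lower of 18) and estrogen receptor targets (Igfbp4 alone called of 6) were among them. FOXO targets (adjusted p = 0.112 with an estimated correlation), DNA repair (p = 0.382) and ribosomal proteins (p = 0.0634) did not. The number of calls was 1194 without D1TA replicate 2, 1233 without Control library a, 1026 with only these 2 groups in the fit and 597 with the 5.8S level as a covariate, chosen after seeing the data. With library medians made equal, 44.6% of the calls were higher, against 59% in the values as deposited. Adjusted over the list alone, 26 mitotic genes and 14 E2F targets were lower and 18 interferon genes were higher.

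D1TA_shPten was compared with Control for the combined labels. Matrix genes rose in 30 of 32 cases, contractile genes in all 19, cholesterol genes in 22 of 24 and interferon genes in 22 of 28, with 4 interferon genes lower. Lum (log2 2.15 ± 0.06), Myh11 (1.75 ± 0.05), Actg2 (1.70 ± 0.03), Ltbp2 (1.44 ± 0.03), Stat1 (1.27 ± 0.04), Cyp51 (1.22 ± 0.04) and Stat2 (1.10 ± 0.04) were among them. Glycolysis and hypoxia genes fell in 14 of 24 cases and rose in 2, with Ndrg1 at -1.26 ± 0.05 and Eno1 at -0.43 ± 0.02. Ribosomal protein genes fell in 23 of 29, and the 4 epithelial markers fell, Cldn4 by 2.05 on the log2 scale. Highest by fold were Wisp2 (53.4 ± 1.43 FPKM), Cemip (36.8 ± 0.736 FPKM), Mfap4, Cpxm1, Il1rn, Penk, Lum, Tmem119, Dkk3 and Cxcl14, at log2 2.04 to 2.90. Lowest were Ccl5, Wfdc2, Cldn4, Cxcl10, Fosb, Stmn2, Cxadr, Sdcbp2, Msln and Tigit, at log2 -2.58 to -1.45. Limma called 6744 genes, 3636 higher and 3108 lower, 295 of them at least 2-fold. The share higher fell from 53.9% to 45.7% with equal medians or quantile normalization. Camera called 11 lists, and TGF-beta targets (12 higher and 1 lower of 18) held with an estimated correlation like matrix, contractile, cholesterol, interferon, glycolysis, ribosomal protein and epithelial genes. The calls of G2/M and mitosis (19 of 30 lower, adjusted p = 0.159 with an estimated correlation), fatty acid synthesis (p = 0.251) and YAP-TEAD targets (p = 0.117) did not.

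**Figure D2:**
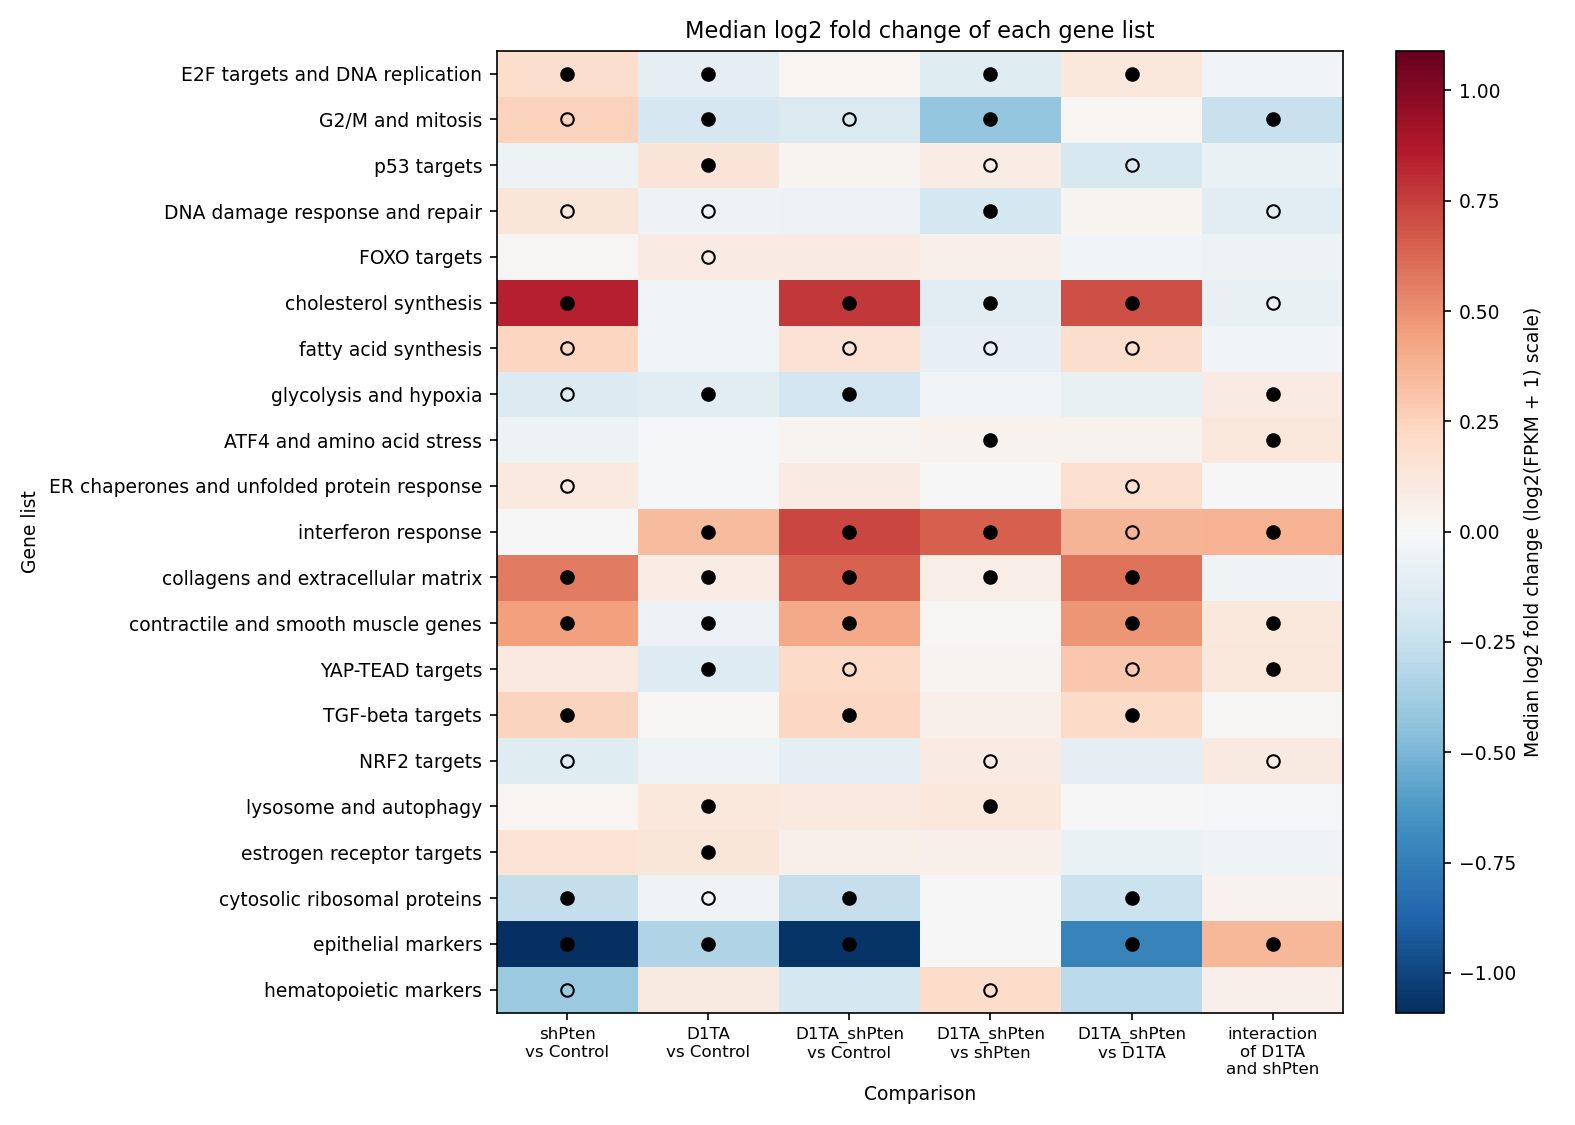
Median log2 fold change of the gene lists that camera called in at least 1 comparison (vertical axis), for each comparison (horizontal axis), as colour, with red higher and blue lower in the group named first. Circles mark lists called by camera at the preset correlation, filled where the call held with an estimated correlation; cholesterol synthesis reaches a median of 0.847 and epithelial markers -1.09 in shPten against Control.

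Within the libraries labelled shPten, D1TA went with more interferon response RNA and less mitotic RNA. Interferon genes rose in 23 of 28 cases and fell in none, with a median fold of 1.57. Isg15, a ubiquitin-like protein, was at 46.7 ± 1.47 FPKM in D1TA_shPten and 17.9 ± 0.978 in shPten. Usp18, which removes Isg15 from proteins, rose by log2 1.09 ± 0.06, Rtp4 by 0.98 ± 0.05 and Bst2 by 0.80 ± 0.04. All 30 genes of G2/M and mitosis fell, with a median log2 change of -0.42, including Birc5 (-0.54 ± 0.04), Aurka (-0.46 ± 0.04), Kif20a (-0.45 ± 0.03) and Kif23 (-0.44 ± 0.03). E2F targets fell in 10 of 34 cases, DNA repair genes in 10 of 25, with Fanca and Rad51 both at -0.31, and cholesterol genes in 7 of 24, with Hmgcs1 at -0.20 ± 0.04. Lysosome genes rose in 11 of 24 cases, ATF4 targets in 5 of 25, with Ddit3 at 0.38 ± 0.07, and matrix genes rose in 12 and fell in 2 of 32. Targets of p53 rose in 4 cases (Perp, Fas and Cdkn1a among them) and Pmaip1 fell by 0.27 on the log2 scale.

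Highest by fold in this comparison were n-R5-8s1 and Lars2, whose locus carries a ribosomal RNA-like repeat (235 ± 108 against 41.4 ± 17.6 FPKM), then Isg15, Ifi27l2a and Oasl2, at log2 1.12 to 3.01. The lowest were Enpp2, the small RNA Scarna3a, Rab26os, Spock3 and the guidance factor Sema3d, at log2 -0.80 to -0.57. Limma called 907 genes, 508 higher and 399 lower, 14 of them at least 2-fold. Camera called 12 lists. Those of interferon, mitosis, E2F, DNA repair, cholesterol, lysosome, ATF4 and matrix genes held with an estimated correlation. The calls of p53 targets (adjusted p = 0.0827 with an estimated correlation), fatty acid synthesis (p = 0.0909), NRF2 targets (p = 0.0916) and hematopoietic markers (p = 0.0916) did not. Adjusted over the list alone, 27 interferon genes were higher, and 30 mitotic genes and 24 E2F targets were lower. The count was 572 without D1TA_shPten replicate 1, 527 without D1TA_shPten replicate 2, 520 without shPten replicate 2 and 548 without shPten replicate 3. With choices made after seeing the data it was 124 with the 5.8S level as a covariate and 555 without the replicates 1 of D1TA and D1TA_shPten.

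Among libraries with D1TA, those also labelled shPten had higher matrix genes (31 of 32 up, 1 down), contractile genes (19 of 19 up), cholesterol genes (21 of 24 up), TGF-beta targets (13 up, 1 down of 18) and E2F targets (16 up, 2 down of 34). Lum (log2 1.92 ± 0.06), Actg2 (1.65 ± 0.03), Cyp51 (1.21 ± 0.04), Ltbp2 (1.05 ± 0.03), Acta2 (0.97 ± 0.02) and Mcm2 (0.46 ± 0.04) were examples. Ribosomal protein genes fell in 24 of 29 cases and epithelial markers in all 4, Cldn4 by 1.63 on the log2 scale. Highest by fold were Mfap4 (41.5 ± 0.489 against 7.60 ± 0.676 FPKM), Cemip, Wisp2, Lum and Myom1. AC117232.1, a short RNA annotated within another gene, was listed at 0 in all 3 D1TA_shPten libraries and at 11.1, 11.2 and 8.95 FPKM in D1TA; it was also listed at 0 in 2 of 3 Control libraries. Pde6h, Ccl5, Cldn4 and Stmn2 were the other lowest genes, at log2 -1.86 to -1.51. Limma called 6012 genes, 3233 higher and 2779 lower, 193 at least 2-fold. Of these calls 53.8% were higher, against 49.5% with equal medians and 48.4% with quantile normalization. Of 12 list calls, 7 held with an estimated correlation. Those of interferon genes (19 higher and 4 lower of 28, adjusted p = 0.0508 with an estimated correlation), YAP-TEAD targets (p = 0.0502), fatty acid synthesis (p = 0.112), p53 targets (3 higher and 14 lower of 27, p = 0.193) and ER chaperones (p = 0.314) did not.

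The interaction asked whether the change with D1TA differed with and without the shPten label. Interferon genes rose more with D1TA in the arm labelled shPten, with 13 of 28 called higher and a median difference of 0.38 on the log2 scale. Ifit1 changed by 0.13 with D1TA alone and by 1 in the shPten arm (interaction 0.87 ± 0.09, adjusted p = 0.000939 by limma). Ccl5, which is not in the interferon list, changed by -0.79 and 0.57. Of these, the change of Ifit1 with D1TA alone and that of Ccl5 in the shPten arm were not called. Mitotic genes fell more in the shPten arm, with 12 of 30 called lower and a median difference of -0.24, including Cdc20 (-0.37 ± 0.06) and Bub1b (-0.30 ± 0.04). In shPten against Control 28 of 30 mitotic genes were higher, with a median log2 change of 0.25. Between D1TA_shPten and D1TA the mitotic list differed little (median 0.0171, 5 higher and 3 lower of 30), so the larger fall was one from a higher level. YAP-TEAD targets (6 of 18 higher, Ankrd1 at 0.75 ± 0.08) and contractile genes (6 of 19 higher, Actg2 at 0.39 ± 0.05) had higher changes in that arm. Ginm1, Wisp2, Penk, Il1rn and Egr3 had the lowest differences, at log2 -1.05 to -0.78. Adjusted over the list alone, 19 interferon genes were higher and 27 mitotic genes lower. Limma called 438 genes, 206 higher and 232 lower, 8 of them at least 2-fold. With equal medians 54.8% of the calls were higher, against 47% as deposited. The count was 278 with no filter on low values, 223 without Control library a, 244 without Control replicate 1, 228 without D1TA replicate 2, 252 and 245 without D1TA_shPten replicates 1 and 2, and 230 and 263 without shPten replicates 2 and 3. Without the replicates 1 of D1TA and D1TA_shPten together, chosen after seeing the data, it was 205.

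**Figure D3:**
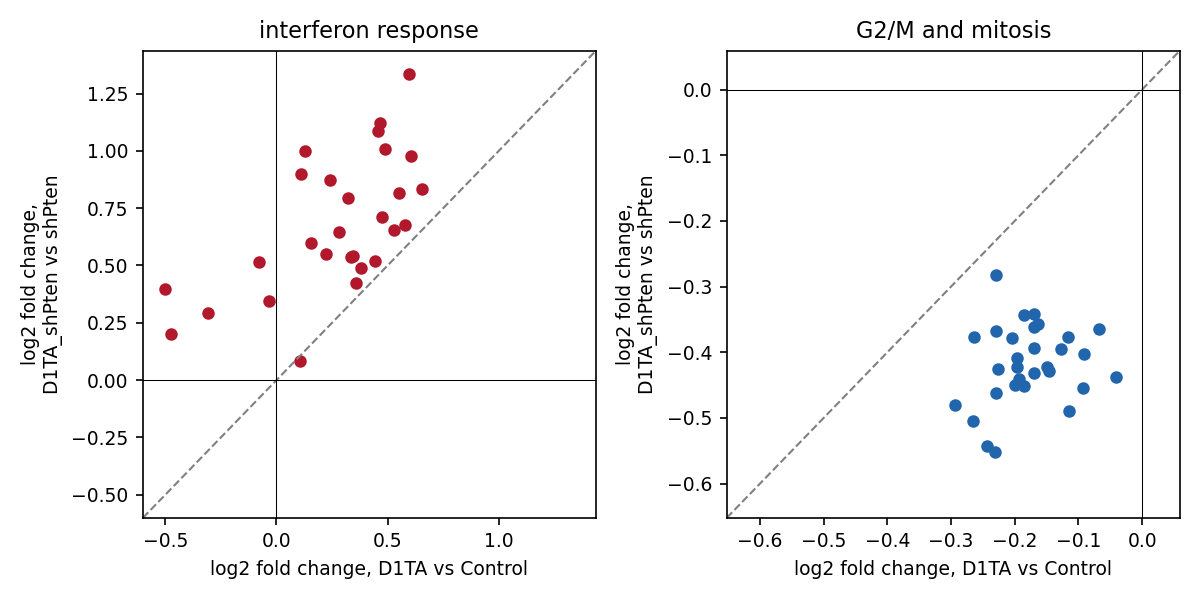
Log2 fold change with D1TA in the arm labelled shPten (vertical axis) against that in the arm without it (horizontal axis) for each measured gene of the interferon and mitosis lists; the dashed line marks equal change. The medians are 0.65 and 0.342 for interferon genes and -0.423 and -0.185 for mitotic genes.

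Across the 13617 tested genes, which are not independent replicates, the D1TA effects in the arms with and without shPten, which share no library, correlated at Pearson r = 0.0566 and Spearman rho = 0.277. This r was smaller than its SE of 0.0671, from a jackknife that left out each library in turn. Among genes called in both, 247 were higher in both and 149 lower in both, against 40.7 and 22.3 for independent lists, and 30 had opposite signs. The shPten effects with and without D1TA correlated at r = 0.478 and rho = 0.737, with 2652 genes higher in both and 2046 lower in both, against 832 and 598, and 39 opposite.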

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

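Of the tests below, those of exchanged labels and of an equal interferon rise in both arms were chosen after their result was seen, and the 5.8S covariate and the list test on the interaction were added after seeing the data. The single genes and lists in the next paragraph were picked out because the change with D1TA differed between the arms with and without the shPten label. Single genes had to be called on the interaction by limma and to be already named by fold or as targets. Folds of shPten or D1TA against Control share libraries with the interaction, so naming by them favours an interaction of the opposite sign. Camera called the lists on the interaction. The mitotic and interferon patterns come from those lists, and Pten was taken up because its RNA goes against the label.

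Single genes with a higher change in the arm labelled shPten were Ccl5 (interaction 1.36 on the log2 scale), Ifi27l2a (1.23), Lce1g (0.92), Cxcl10 (0.90), Ifit1 (0.87), Lce1h (0.85), Tigit (0.77), Sprr2k (0.75), Isg15 (0.74), Rsad2 (0.67), Oasl2 (0.66), Cdkn1c (0.63) and Tnfaip3 (0.47). A lower change was measured for Ginm1 (-1.05), Wisp2 (-0.82), Penk (-0.81), Il1rn (-0.79), Egr3 (-0.78), Abi3bp (-0.77), Sema3d (-0.70), Tmem119 (-0.62), Rab26os (-0.61), Notch3 (-0.51), Cxcl14 (-0.49), Gas1 (-0.47), Pltp (-0.41), Dkk3 (-0.38), Stmn2 (-0.34) and Cemip (-0.30). Among lists, the median interaction was 0.38 for interferon genes, 0.36 for epithelial markers, 0.13 for YAP-TEAD targets, 0.12 for contractile genes, 0.11 for ATF4 targets, 0.099 for NRF2 targets (adjusted p = 0.0828 with an estimated correlation), 0.088 for glycolysis and hypoxia, -0.084 for cholesterol synthesis (p = 0.0889), -0.12 for DNA repair (p = 0.182) and -0.24 for G2/M and mitosis. Ccl5 and Cxcl10 were lowest by fold in shPten against Control, so a further fall with D1TA could hardly show in that arm. Their interactions include changes of -0.79 and -0.5 with D1TA without shPten. In that arm Tigit also changed by -0.84, Lce1h by -0.59, Sprr2k by -0.52, Rsad2 by -0.47 and Tnfaip3 by -0.43. In the arm labelled shPten these genes changed by -0.07, 0.26, 0.23, 0.2 and 0.04. Lce1g changed by -0.45 without and 0.47 with shPten, and Cdkn1c by -0.29 and 0.34. Isg15 (0.6), Oasl2 (0.47), Ifit1 (0.13) and Ifi27l2a (0.02) did not fall with D1TA without shPten. Epithelial markers, like Ccl5 and Cxcl10 lower in shPten than in Control, had a median change with D1TA of -0.327 without shPten and -0.00563 in the arm labelled shPten.

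Pten RNA was not lower in the 6 libraries labelled shPten than in the other 6, though it differed by -0.0862 (log2) between D1TA_shPten and D1TA, a difference that limma called with the replicate block (adjusted p = 0.0392) and, at -0.146, with quantile normalization (0.0304), but not in the fit of all 12 libraries as deposited (0.244). An exchange of the shPten and Control labels would put Pten higher in shPten, by at least 0.5 on the log2 scale, and it was higher by 0.10 ± 0.06 (SE). Reads of another gene annotated at the same locus are argued against by an exon overlap of 0% of the Pten exonic bases. Reads from paralogs or pseudogene copies elsewhere were not tested. Cultures from embryos of different sex are argued against by a largest difference of -0.27 (log2) among Xist and Y-linked genes. Loss of PTEN function without loss of its RNA may exist and stays open: FOXO targets, which AKT restrains, had a median log2 change of -0.03 in D1TA_shPten against D1TA and 0.0146 in shPten against Control, with members going both ways. Whether the hairpin acted on Pten at all was not tested, and no control hairpin was named. The differences of the libraries labelled shPten can therefore not be credited to loss of PTEN from these data.

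Mitotic transcripts were fewer with D1TA in the arm labelled shPten. With the 5.8S level as a covariate, 89.6% of the median change was left, so 5.8S as it varies within groups accounts for little of it. The 5.8S levels of D1TA_shPten (8214 to 29770 FPKM) and shPten (773.2 to 2915 FPKM) did not overlap. A ribosomal RNA difference tied to the groups therefore cannot be told apart from D1TA and stays open. A p53 response, as Cre activity or DNA damage could give, stays open: the p53 list was called higher (median log2 change 0.079, adjusted p = 0.00046 by camera), as it requires, though not with an estimated correlation (adjusted p = 0.0827), and with 4 members up and 1 down of 27. Against p53 as the source of the larger mitotic fall in this arm, the p53 list rose more in D1TA against Control (median 0.14, 11 up and 2 down, adjusted p = 0.0277 with an estimated correlation), where the mitotic median was -0.185 against -0.423 here, and its median interaction was -0.0716, which camera did not call (adjusted p = 0.0726). The mitotic falls began at different levels, which limits this argument: the mitotic median was 0.25 in shPten against Control and 0.0171 in D1TA_shPten against D1TA. Exposure to 4-hydroxytamoxifen cannot be told apart from the D1TA allele, because the labels name the drug without D1TA for 0 of the 12 libraries and do not say whether the others received it, and an effect of the cyclin D1 mutant itself remains a hypothesis.

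Interferon response transcripts rose with D1TA in that arm. A single deviating library is argued against, as the lowest median with 1 of the 6 libraries left out was 95.7% of the value from all of them. With the 5.8S level as a covariate 98% of the median change was left, so 5.8S as it varies within groups accounts for little of it. A ribosomal RNA difference tied to the groups cannot be told apart from D1TA here either and stays open. The median interaction of 0.376 is the value that picked this result out, so it is no separate test. A rise of the same size in both Pten arms therefore has no test here apart from that interaction. By limma 13 of 28 genes were called higher and 0 lower, and the camera call held with an estimated correlation (adjusted p = 0.00256). Exposure to 4-hydroxytamoxifen, confounded with D1TA as above, was not tested for these genes and may contribute; so may the D1TA allele.

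Chance was weighed by other splits of the libraries. With 10 splits of 3 against 3 a share under 0.05 cannot be reached. The real split gave 6435 genes for shPten against Control, where the highest other gave 5, and 1852 against 4 for D1TA against Control. It gave 6744 against 1 for D1TA_shPten against Control, 907 against 4 for D1TA_shPten against shPten and 6012 against 3 for D1TA_shPten against D1TA. In each, 1 split, the real one, gave as many genes. For the interaction, 1 of 100 draws of the labels, the real one, gave as many genes after both main effects were removed, 438 against at most 3 in the others. Random draws mix libraries of different groups, so their low counts say only that the libraries group by label. They cannot tell an effect of the labels from any other difference between the groups of libraries.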

How the results depend on the processing

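The 5.8S level as a covariate, leaving out both libraries with the most 5.8S, leaving out genes under 300 exonic bases, the fit of 9 libraries without a block, the permutation within each arm and the list test on the interaction were chosen after seeing the data. Of 9546 alternatives of 409 values of named genes, 9040 gave the same direction and side of the threshold, 489 lost the call, 11 gained one and 6 changed sign.

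All 6 changes of sign were those of Pten, D1TA_shPten vs shPten, which was not called and lay at -0.002 (log2). It was 0.112 with the 5.8S covariate and 0.0261 with both libraries with the most 5.8S left out, and -0.0346 to 0.0261 with 1 library left out. The difference of Pten by the shPten label was 0.00679 (log2, exact p = 0.913), -0.0436 with quantile normalization (exact p = 0.459), -0.0862 in the replicate block for D1TA_shPten against D1TA (limma adjusted p = 0.0392) and -0.0259 to 0.0453 with 1 library left out. The cause was not tested. Ccnd1 by the D1TA label was 0.0799 (log2, exact p = 0.569, and 0.005 with labels permuted within each arm, which removes the shPten difference), 0.0644 in the block for D1TA_shPten against shPten (limma adjusted p = 0.0485) and 0.032 to 0.13 with 1 library left out. Both block values compare 3 with 3 libraries within 1 arm; without the block the same 9 libraries gave the same differences with adjusted p = 0.247 for Pten and 0.133 for Ccnd1. Across genes no pairing was seen: correlations of libraries with the same number, after removal of group means, ran from -0.0833 to 0.025 in 9 pairs. Pairing is not excluded by this. Pten rose with the replicate number in D1TA (24.7, 26.7 and 28.6 FPKM), D1TA_shPten (24, 24.8 and 26.2) and shPten (24.1, 25.1 and 25.9). The block also raised the calls in the same 9 libraries, from 733 to 989 for D1TA_shPten against shPten and from 5802 to 6247 for D1TA_shPten against D1TA.

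With the added demand of a 2-fold change, which leaves fewer genes by construction, counts were 237 for shPten against Control, 10 for D1TA against Control, 295 for D1TA_shPten against Control, 14 for D1TA_shPten against shPten, 193 for D1TA_shPten against D1TA and 8 for the interaction. With the 5.8S covariate 597 genes were called for D1TA against Control and 124 for D1TA_shPten against shPten; the covariate differs between the groups and takes part of their difference. Without both libraries with the most 5.8S, which leaves fewer libraries, 555 were called for D1TA_shPten against shPten and 205 for the interaction. With only the groups compared, D1TA against Control gave 1026, and with no filter the interaction gave 278 and the shPten effects with and without D1TA correlated at 0.411, against 0.478 (jackknife SE 0.045); the cause was not tested. With an estimated correlation, 7 lists instead of 14 were called for shPten against Control and 7 instead of 12 for D1TA_shPten against D1TA.

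With 1 library left out, counts were 5673 to 6503 for shPten against Control, 1194 to 1792 for D1TA against Control, 5961 to 6807 for D1TA_shPten against Control, 520 to 922 for D1TA_shPten against shPten, 5298 to 5981 for D1TA_shPten against D1TA and 223 to 366 for the interaction. Lists called in the same order were 14 to 15, 12 to 15, 11 to 12, 11 to 15, 12 to 13 and 10 to 12. The correlation of the D1TA effects was 0.029 to 0.0944 and that of the shPten effects 0.438 to 0.479. The value 1194 was without D1TA replicate 2; without Control library a it was 1233. For D1TA_shPten against shPten, the count was 572 and 527 without D1TA_shPten replicates 1 and 2 and 520 and 548 without shPten replicates 2 and 3. For the interaction it was 223 without Control library a, 244 without Control replicate 1, 228 without D1TA replicate 2, 252 and 245 without D1TA_shPten replicates 1 and 2, and 230 and 263 without shPten replicates 2 and 3.

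Depth, known only as an estimate, limits the precision of low genes.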

Other observations

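Of the Y-linked genes, Uty was at 5.92 ± 0.554 FPKM in shPten and 6.25 ± 0.496 in D1TA_shPten against 7.33 ± 0.379 in Control and 7.46 ± 0.404 in D1TA (SD, n = 3). Eif2s3y was at 25.6 ± 2.19 and 24.8 ± 1.77 against 30.6 ± 2.86 and 30.3 ± 3.03 FPKM in the same order. Kdm5d was at 4.19 ± 0.139 and 4.58 ± 0.590 against 3.76 ± 0.201 and 4.15 ± 0.464 FPKM. Ddx3y was at 24.0 ± 1.35 FPKM in Control, 25.1 ± 1.90 in shPten, 23.5 ± 1.90 in D1TA and 25.4 ± 1.42 in D1TA_shPten (SD, n = 3), and Xist was under 0.02 FPKM in each group mean.

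Other features that carry ribosomal RNA-like sequence moved with n-R5-8s1. Mir6236 was at 45800 to 82140 FPKM in D1TA, 20240 to 42200 in D1TA_shPten, 6846 to 25100 in Control and 2915 to 9357 in shPten, and Lars2 at 258 to 528, 142.7 to 353.4, 52.22 to 153.5 and 25.77 to 60.4 FPKM in the same order. The 10 highest features held 20.17% to 36.4% of a library's summed FPKM.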
